A study of Homo sapiens with 8 samples.

How the data were processed

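CCRF-CEM is an established human T-cell acute lymphoblastic leukaemia (T-ALL) line. Per the labels, cells were either left untreated or pretreated with 1 µM OICR-9429 for 1 h, mixed into a type I collagen solution of 1.7 mg/mL and kept in the polymerized gel for 1 h before RNA was taken. OICR-9429 is a small molecule that binds WDR5 in the pocket through which WDR5 contacts MLL-family histone H3 lysine 4 methyltransferases. The labels name 8 samples, 4 untreated and 4 treated, as biological replicates numbered 1 to 4 in each group. They describe the control cells as untreated and mention no solvent given to them, so the comparison is of cells given OICR-9429 with cells not given it. Whether the control cells were held for the same 1 h before the gel is not known here. The labels do not say whether the replicates came from separate passages or days, so p-values measure the spread between these samples.

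The values are log2 expression values per probe set, as the authors deposited them. Per the submitters' processing notes, RMA (background correction, normalization between arrays and summary of probes) and Transcriptome Analysis Console were used, and their versions are not given in the sources used here. Per the labels, RNA was labelled with the GeneChip WT PLUS kit. The genome build behind the probe sets is not given in the sources used here, and no coordinates were used. The table held 21448 probe sets on each of 8 arrays. Scanner files were not used here, so neither background signal nor scan batch was examined. Array medians ran from 6.38 to 6.46, and no pair of arrays held identical values. The number of arrays limits the precision.

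Probe sets were named from the platform annotation, with symbols looked up by Entrez ID in a RefSeq gene table of assembly GRCh38.p14, which was used for names only. Of the probe sets, 17709 had 1 gene symbol, 0 had several and 3739 had none here. A gene with more than 1 probe set (20 genes, of which 7 had fold changes of opposite sign) was represented by the probe set with the highest mean over all arrays, which left 17661 genes for tests of gene lists.

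Groups were compared with limma (version 3.58.1, R 4.3.3), with lmFit and eBayes on the log2 values, all 8 arrays, two-sided tests and no covariate. Benjamini-Hochberg adjustment was made over all probe sets, with a threshold of 0.05. Gene lists were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over 35 lists. The 35 lists, the tests, the rule for named genes and most alternatives were fixed before the data were examined. The lists hold 1060 symbols, of which 921 entries (900 distinct genes) were measured. They cover the WDR5 complexes and other H3K4 regulators, HOX and MEIS genes, ribosomal proteins, ribosome biogenesis, stress and signalling responses, metabolism, cell cycle and histone genes, T-cell and NOTCH genes, adhesion, proteolysis, motility, mechanical response, the nuclear envelope, chromatin, apoptosis, migration receptors, splicing, KRAB zinc fingers and markers of 5 other kinds of cell. The named genes were, among probe sets with 1 symbol, the 12 with the largest and the 12 with the smallest fold change past the threshold, filled up where fewer passed by those with the smallest unadjusted p in that direction. To these were added WDR5, RBBP5, ASH2L, DPY30, KMT2A and MYC, and the members of each list with the smallest unadjusted p. Of the genes this rule takes, 1 is not reported here.

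The replicate numbers come from the sample titles. Deviations from the group means correlated between the untreated and treated array of the same number, across probe sets, at 0.696, 0.748, 0.566 and 0.865 for numbers 1 to 4, and each array correlated best with its own number. By a limit of 0.1 set in advance, the numbers pair the samples. A fit with the number as a block (the replicate block) was therefore run beside the comparison without it. That block found 1191 probe sets at an unadjusted p under 0.05, against 105 without it. Where the block is not named, SEs and p-values of the treatment comparison come from the fit without it. That fit ignores the pairing, and its median SE was 0.22, against 0.11 with the block. Differences between numbers were tested with limma in a model with number and treatment, each number against the mean of the other numbers and all numbers at once. Those tests were chosen after the data had been seen. They have 2 arrays per number and 3 residual degrees of freedom before eBayes pooling. Their SEs and p-values rest on how the treated-minus-untreated difference varies over the numbers. Since same-numbered arrays pair, they do not measure the spread between separate cultures.

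Both fits were tested on simulated data built on the deposited values, with 200 probe sets changed in each of 20 runs over 21448 probe sets. Without the block, 0.149% of probe sets changed 1.5-fold, 12.2% of those changed 2-fold and 77.8% of those changed 4-fold were recovered. With the replicate block the shares were 27.5%, 69.8% and 95.7%. A list of 30 genes shifted by 0.3 on the log2 scale had an unadjusted camera p under 0.05 in 100% of runs in either fit, and an unshifted list in 0%. That is at the preset correlation, with residuals drawn independently for each gene and no adjustment over lists, so it gives no rate for the adjusted calls.

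Alternatives were a further quantile normalization, median centring, filters at the 25th percentile and the median of mean level, probe sets with 1 symbol alone, eBayes with a trend and robust variance, array weights, the replicate block, other thresholds, camera with an estimated correlation or on ranks, fry, and leaving out each array. Added after seeing the data were block fits with other variance models, filters or 1 pair left out, and a random block. Figures were drawn with matplotlib 3.10.9 (Python 3.11.15). Probe sets on the Y chromosome were counted but are not named.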

Results

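Gene expression was measured with Affymetrix arrays in CCRF-CEM T-ALL cells held for 1 h in a collagen gel, with or without 1 h of pretreatment with 1 µM OICR-9429. There were 4 arrays per group, with 21448 probe sets on each, and the middle of each array's values lay between lower quartiles of 4.52 to 4.69 and upper quartiles of 8.08 to 8.40 on the log2 scale. The design asks which transcripts differ when the WDR5 inhibitor precedes culture in a 3D matrix.

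The 8 arrays grouped by replicate number and not by treatment. Replicate number held 85.5% of the variance over all probe sets, treatment 3.93% and the remainder 10.6%. The first principal component (64.8% of variance) set both arrays of number 4 apart from the other 6, and the second (15.3%) set number 1 against number 2. Same-numbered arrays correlated across probe sets at 0.987 to 0.995.

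**Figure D1:**
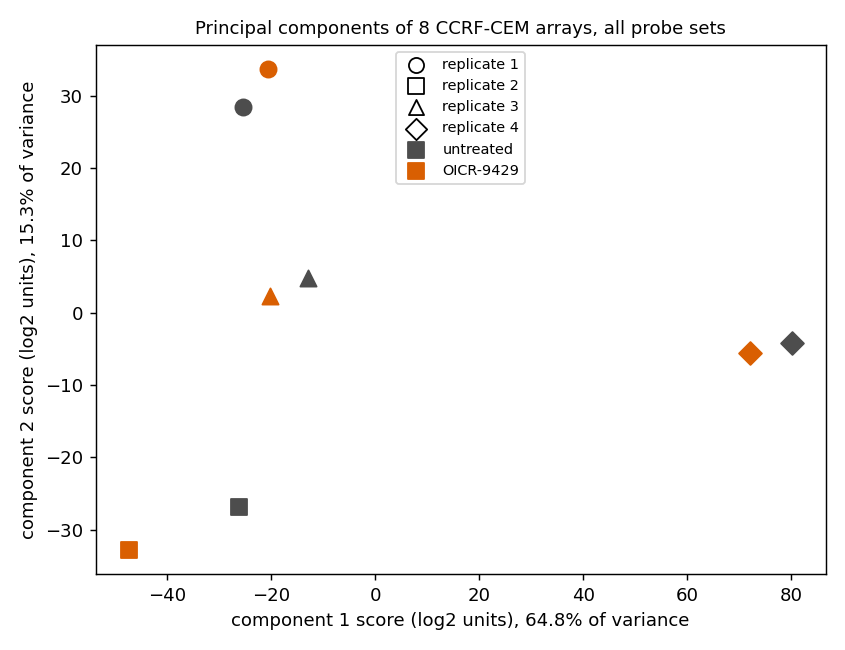
Scores of the 8 arrays on the first 2 principal components (log2 units), with colour for treatment and symbol for replicate number. Both arrays of number 4 lie at 72.1 and 80.2 on component 1, and the other 6 lie between -47.3 and -12.9.

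No transcript passed the test for a difference between OICR-9429 and untreated cells. With limma, 0 of 21448 probe sets passed an adjusted p of 0.05 (0 higher, 0 lower, smallest adjusted p 1), and 105 had an unadjusted p under 0.05, of which 32 were higher and 73 lower with OICR-9429. Chance alone gives 1072.4 such probe sets when arrays are independent. With the replicate block, 0 passed again (smallest adjusted p 0.841), and 1191 had an unadjusted p under 0.05, 469 higher and 722 lower. Turning the sign of whole pairs gave 806 to 1537 such probe sets with that block, and 2 of 8 arrangements, the real one included, gave 1191 or more. The largest fold change was 0.96 on the log2 scale and the smallest -0.78, so 0 probe sets differed by 2-fold and 20 by 1.5-fold. An unadjusted p under 0.05 together with a 1.5-fold difference was met by 9 probe sets (3 higher, 6 lower), and by 19 with the replicate block.

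The intervals show, for each probe set, which sizes of change its values leave open. They are not adjusted for the number of probe sets. Signal over background is not known, and a probe set without it can have a narrow interval whatever its transcript does. The median half-width of the 95% interval of a log2 fold change was 0.50 without and 0.26 with the replicate block. With the block, the interval lay within 2-fold for 21409 probe sets (99.8%) and within 1.5-fold for 19448 (90.7%).

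The 12 genes nearest the threshold in the higher direction did not pass it, and 11 of them lay below the median level of all probe sets. HS6ST2, a heparan sulfate 6-O-sulfotransferase, measured 4.08 ± 0.10 (SD, n = 4) in untreated and 4.55 ± 0.18 (SD, n = 4) in treated cells, a log2 difference of 0.47 ± 0.15 (SE). FGD4, an exchange factor for the small GTPase CDC42, measured 4.17 ± 0.34 and 4.74 ± 0.20 (SD, n = 4 each). IL1A, which encodes interleukin 1 alpha, had the largest difference of the 12, from 3.31 ± 0.34 to 3.88 ± 0.31 (SD, n = 4 each), a log2 difference of 0.57 ± 0.22 (SE). The others were FGG (fibrinogen gamma chain), PYDC2, AKAP6 (an anchor of protein kinase A), RYR2 (the cardiac ryanodine receptor), A4GNT, CCDC126, MTURN, KLHL41 and LHX2, with log2 differences between 0.39 and 0.56. CCDC126, at 6.82 ± 0.23 and 7.34 ± 0.31 (SD, n = 4 each), was the only one of the 12 above the median level.

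All 12 genes nearest the threshold in the lower direction also failed it and lay below the median level. SULT1C3, a cytosolic sulfotransferase, measured 3.53 ± 0.07 in untreated and 3.05 ± 0.09 in treated cells (SD, n = 4 each), a log2 difference of -0.48 ± 0.14 (SE). AMER2, C1QTNF6, NOBOX (an oocyte homeobox gene), KRTAP5-8 (a keratin-associated protein), KCNK15 (a potassium channel), CMTM8, PAQR5, GOLGA8DP, HS3ST3B1 (a heparan sulfate 3-O-sulfotransferase) and SHISAL1 had log2 differences between -0.59 and -0.41. Each of the 24 genes differed in its stated direction in 4 of 4 pairs, and the smallest adjusted p among them with the replicate block was 0.841 (limma). The genes were picked on these same arrays, which favours such agreement, so it is no separate evidence of a change.

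**Figure D2:**
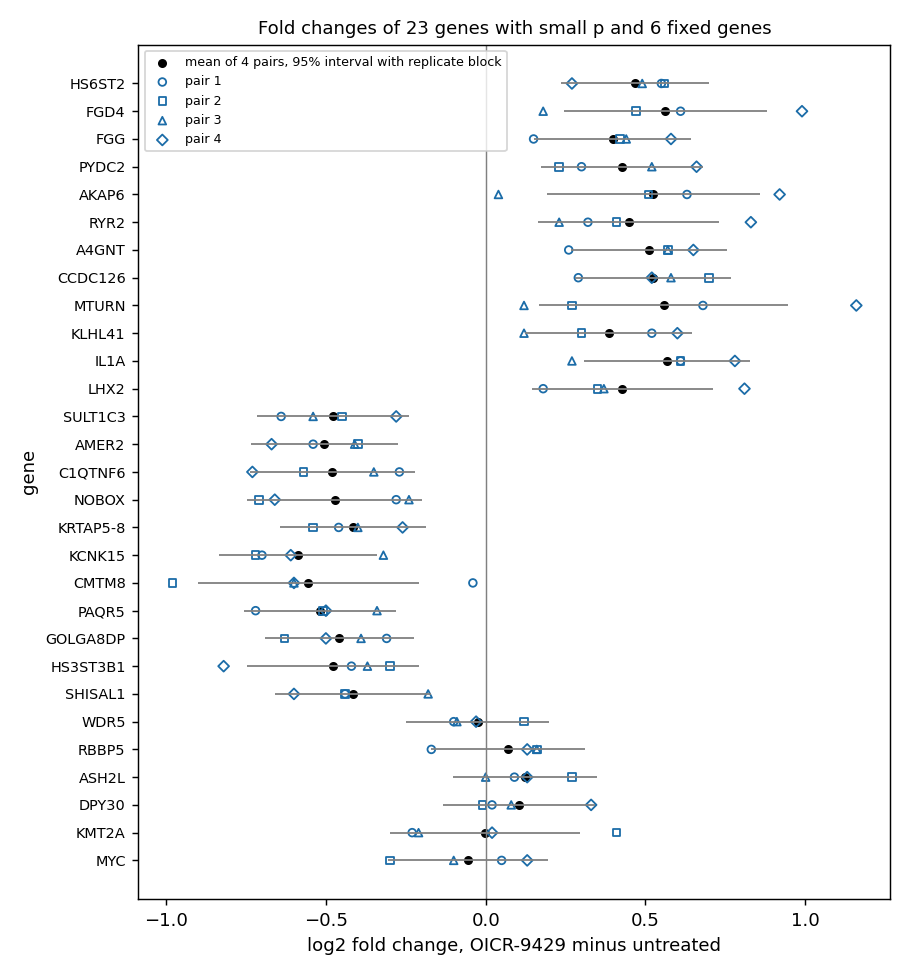
Log2 fold changes (OICR-9429 minus untreated) of 23 of the 24 genes with the smallest unadjusted p and of 6 genes fixed in advance, with open symbols for the 4 pairs and black points with 95% limma intervals from the replicate block. The intervals of the 6 fixed genes include 0, and those of the 23 genes are not adjusted for their selection.

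The target of the inhibitor and its partners did not pass the test. WDR5 measured 9.54 ± 0.42 in untreated and 9.52 ± 0.34 in treated cells (SD, n = 4 each), a log2 difference of -0.03 ± 0.25 (SE). With the replicate block that SE was 0.097. RBBP5, ASH2L and DPY30, which form the core of the H3K4 methyltransferase complexes with WDR5, differed by 0.07, 0.12 and 0.10, and KMT2A, which encodes MLL1, by -0.0025. For ASH2L, at 9.16 ± 0.11 and 9.28 ± 0.06 (SD, n = 4 each), that is more than either SD, and 0 of 4 pairs were lower. Of the 18 measured members of the WDR5 complexes, 9 had a difference above 0 and 9 below it, 0 passed, and the list mean was 0.0079 (limma's camera, adjusted p = 0.831). Among the 16 H3K4 demethylases and readers, 12 lay above 0 and 0 passed, with a mean of 0.06 (camera, adjusted p = 0.63). PHF8 stood at 0.13 and KDM5A at 0.12. With the replicate block this list had adjusted p = 0.269 (camera), and 0.885 with an estimated correlation. Its mean was above 0 in 4 of 4 pairs, and chance gives the same sign in all 4 pairs for 12.5% of lists.

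Gene groups with known links to WDR5 and MLL did not pass either. Cytosolic ribosomal protein genes, many of which carry WDR5 at their promoters, had 33 of 46 members below 0 and a mean of -0.03 (camera, adjusted p = 0.637), with RPL35 at -0.10 and RPL18 at -0.11. The pairs of this list went both ways, at 0.096, -0.125, -0.043 and -0.055 for numbers 1 to 4. MYC measured 10.12 ± 0.33 in untreated and 10.07 ± 0.46 in treated cells (SD, n = 4 each), and the 31 ribosome biogenesis genes that respond to MYC had a mean of 0.02 (adjusted p = 0.724). Of 20 HOX, MEIS and related genes 9 were measured, with a mean of 0.08 (adjusted p = 0.63), the leukaemia cofactor PBX3 at 0.30 and HOXA2 at 0.20. NOTCH targets had a mean of -0.02 (adjusted p = 0.831), with HES4 at -0.29 and HEYL at -0.23. T-cell identity genes, with 22 of 32 members below 0, had a mean of -0.05 (adjusted p = 0.63), and LMO1 and CD8B stood at -0.24 and -0.18. The pairs of this list went both ways, at 0.03, -0.14, -0.13 and 0.02. With the replicate block it had adjusted p = 0.269 (camera).

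Genes that a 3D matrix might engage showed no shift past the threshold. Integrins and adhesion receptors (31 measured) had a mean of -0.01 (camera, adjusted p = 0.94), with CD151 at 0.19 and ITGB5 at -0.18. Matrix proteases and their inhibitors (28 measured) had a mean of -0.03 (adjusted p = 0.831), and MMP14, a membrane-bound collagenase, measured 5.57 ± 0.32 and 5.11 ± 0.16 (SD, n = 4 each). Actin and motility genes averaged 0.02 (adjusted p = 0.831), SRF and YAP targets -0.03 (adjusted p = 0.646) and chemokine and cytokine receptors -0.06 (adjusted p = 0.641). Among the receptors CXCR3 stood at -0.28 and CXCR6 at -0.55, with CXCR6 pairs of -0.48, -0.68, 0.35 and -1.39 and a difference of -0.28 without untreated replicate 4. The nuclear envelope list averaged 0.03 (adjusted p = 0.641), with LMNA at -0.18 and NUP133 at 0.24, and the heterochromatin and Polycomb list 0.03 (adjusted p = 0.646), with SETDB1 at 0.18.

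Stress, signalling and metabolic lists gave 0 members past the threshold. The p53 targets had 17 of 22 members above 0 and a mean of 0.08 (camera, adjusted p = 0.48), with PPM1D at 0.24 and SESN1 at 0.17. Heat shock genes averaged 0.07 (adjusted p = 0.63). With the replicate block both lists had adjusted p = 0.135 (camera), and 0.885 with an estimated correlation. Both means were above 0 in 4 of 4 pairs. Of all 35 lists, 5 had means of the same sign in all 4 pairs. Besides these and the H3K4 demethylases and readers, they were ribosome biogenesis genes (above 0) and chemokine and cytokine receptors (below 0). Chance gives such agreement in 12.5% of lists if the pairs are independent, and 5 of 35 is near that share. The agreement is therefore no separate evidence of a shift. Immediate early genes averaged -0.01 (adjusted p = 0.831), and KLF4 measured 4.93 ± 0.35 and 4.32 ± 0.39 (SD, n = 4 each). The NF-kappaB, unfolded protein, hypoxia, sterol and interferon lists had means of -0.0032, 0.0088, 0.03, 0.05 and -0.03 (adjusted p = 0.94, 0.934, 0.647, 0.641 and 0.647). With the replicate block the sterol list had adjusted p = 0.33 (camera). The list of aryl hydrocarbon receptor and NRF2 targets averaged 0.03 (adjusted p = 0.831), with GCLC, a subunit of the enzyme that limits glutathione synthesis, at 0.51 and OSGIN1 at -0.46. The apoptosis and oxidative phosphorylation lists averaged 0.0029 and -0.01 (adjusted p = 0.853 and 0.943). For the NF-kappaB, immediate early and oxidative phosphorylation lists, and for the myeloid markers, the mean differed in sign from the median or from the direction camera gave.

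Cell cycle and RNA processing lists lay within 0.1 of 0. Replication genes averaged 0.01, mitotic genes 0.04 and splicing genes 0.04 (camera, adjusted p = 0.831, 0.63 and 0.63). With the replicate block the mitotic and splicing lists had adjusted p = 0.295 and 0.269 (camera). Histone genes had 41 of 48 members below 0 and a mean of -0.06 (adjusted p = 0.63), but the pairs went both ways, at 0.08, -0.22, -0.14 and 0.04 for numbers 1 to 4. With the replicate block the list had adjusted p = 0.0769 (camera), and in block fits chosen after seeing the data 0.000139 with trend and robust variance, 0.000438 with the median filter, and 0.00104, 0.886, 0.554 and 0.00613 without pairs 1 to 4. These calls rest on the preset correlation: with the replicate block the list had adjusted p = 0.885 with an estimated correlation (camera) and 0.756 with fry, and the later block fits were not run that way. KRAB zinc finger genes, whose transcripts are short-lived, had 30 of 39 members above 0 and a mean of 0.09 (adjusted p = 0.48), with ZNF155 at 0.22 and ZNF20 at 0.17. This was the only list past the threshold with the planned replicate block (camera, adjusted p = 0.0388), and there adjusted p = 0.885 with an estimated correlation. The other sign arrangements of the pairs gave 0 to 6 lists, and 5 of 8, the real one included, gave 1 or more. Its pairs stood at -0.07, 0.15, 0.04 and 0.24, and without pair 2 or pair 4 the block gave adjusted p = 0.188 and 0.328 in limma's camera.

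Markers of 5 other kinds of cell did not pass the threshold. B-cell, myeloid, erythroid and megakaryocyte, fibroblast and epithelial, and NK and cytotoxic markers averaged -0.01, 0.0089, -0.10, -0.07 and -0.02 (camera, adjusted p = 0.831, 0.94, 0.63, 0.63 and 0.94). With the replicate block the erythroid and megakaryocyte list and the fibroblast and epithelial list each had adjusted p = 0.135 (camera). Over all 35 lists, 0 passed with camera (smallest adjusted p 0.48), with an estimated correlation (0.981) or with fry (0.996). Of the 921 list entries, 2 (KLF4 and MMP14) had an unadjusted p under 0.05, against 29 with the replicate block. Over all probe sets the block gave 5.55%, a larger share than in the lists. Adjusted over the list alone, 0 members passed without the block, and with the replicate block KLF4 (adjusted p = 0.0358, limma) and GCLC (adjusted p = 0.0175, limma) did, while 0 passed when adjusted over all probe sets.

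**Figure D3:**
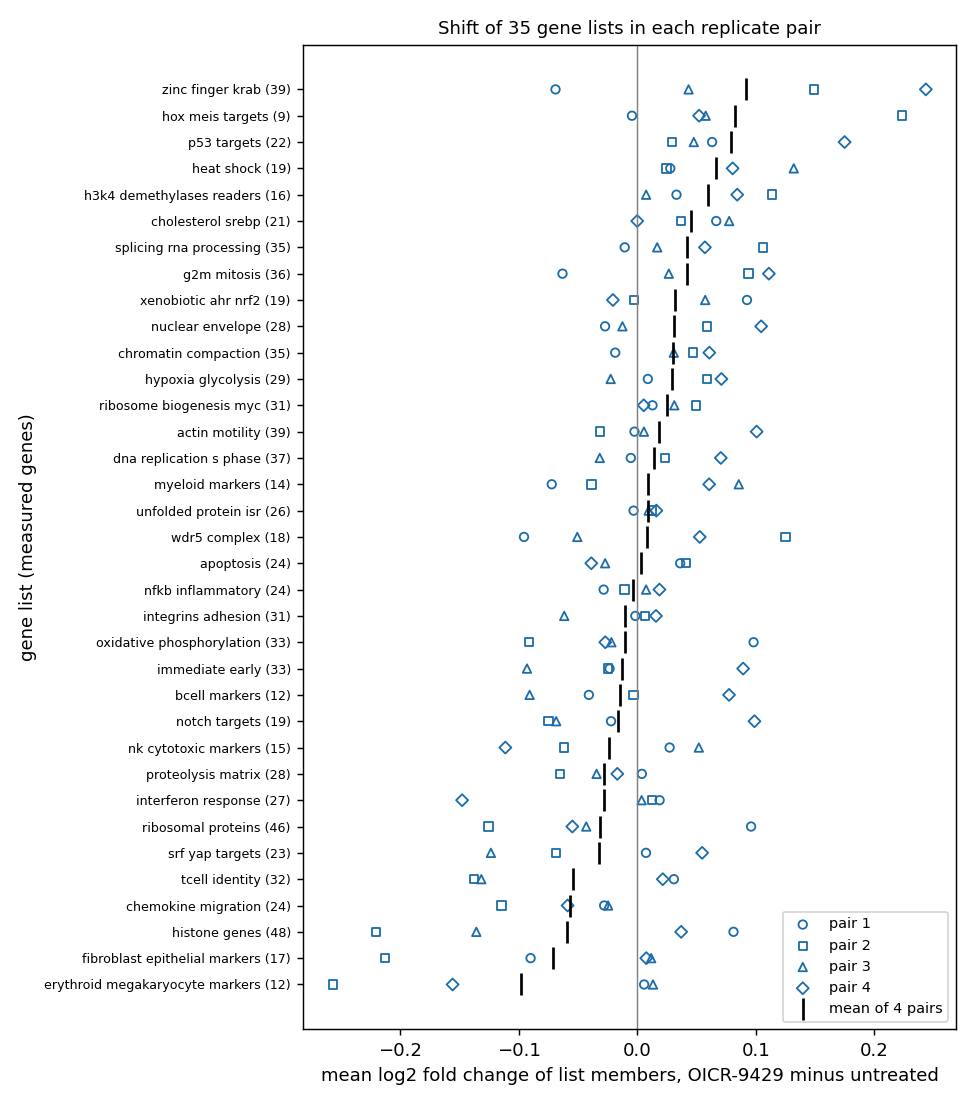
Mean log2 fold change (OICR-9429 minus untreated) of the measured genes of each of 35 lists, with open symbols for the 4 replicate pairs and black bars for their mean. The means lie between -0.10 and 0.09.

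Fold changes were compared between the 4 pairs. Correlations of fold changes across probe sets between pairs ran from -0.056 to 0.122 (mean 0.0205, and 2 of 8 sign arrangements were as high), where genes are not independent replicates. In 2693 probe sets (12.6%) all 4 pairs went the same way, and chance gives 12.5%. In 158 probe sets (0.737%) the values of the groups did not overlap, and chance gives 2.86% for arrays that vary independently, which these do not. The other splits that part all 4 pairs gave 128 to 166 such probe sets, and 5 of the 8, the real one included, gave 158 or more.

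The replicate numbers themselves differed widely: 10791 probe sets (50.3%) passed limma's test of any difference between numbers. Number 1 had lower hypoxia and glycolysis genes (23 of 29 lower, median -0.80 against the other numbers) and lower immediate early genes (23 of 33 lower, 1 higher, median -0.75), and higher ribosome biogenesis genes (24 of 31 higher, median 0.72). EGR1, an immediate early transcription factor, was lower by a log2 difference of -3.69 ± 0.14 (SE), JUN by -2.75 ± 0.11 and the hypoxia-induced BNIP3 by -2.63 ± 0.11, while SRM, which makes spermidine, was higher by 1.63 ± 0.12. Markers of other kinds of cell also differed at number 1: 3 of 14 myeloid and 4 of 12 erythroid and megakaryocyte markers were lower and 0 higher (medians -0.34, or -0.12 without number 4, and -0.24, or -0.40 without number 3), with camera adjusted p = 0.0201 and 0.0443 and, with an estimated correlation, adjusted p = 0.368 and 0.551. Number 4 had higher histone genes (46 of 48, median 0.75) and hypoxia genes (24 of 29, median 0.73), and lower KRAB zinc finger genes (26 of 39, with 4 higher, median -0.84) and WDR5 complex genes (13 of 18, median -0.64). Among the last, KMT2C stood at -2.52 ± 0.18 (SE) and KMT2A at -1.52. Markers of other kinds of cell differed at number 4 as well: 8 of 14 myeloid markers were higher and 0 lower (median 0.41, camera adjusted p = 0.0358, and adjusted p = 0.368 with an estimated correlation), among them CD68 at 1.68 ± 0.13 (SE). The fibroblast and epithelial (6 higher, 1 lower), erythroid and megakaryocyte (4 higher, 1 lower), NK and cytotoxic (3 higher, 0 lower) and B-cell (1 higher, 3 lower) markers had medians of 0.35, 0.32, 0.26 and 0.11 there and did not pass, and without number 1 the erythroid and NK medians were 0.18 and 0.15. The marker lists are dim, with mean levels of 5.085 to 6.27. Across probe sets, differences correlated with mean level at 0.233 for number 1 and -0.232 for number 4. Shifts of dim lists at these numbers cannot be told apart from that trend. Over the 4 numbers 46 of 140 list tests passed with the preset correlation and 0 with an estimated correlation. Leaving out pair 4 lowered the count of differing probe sets to 2979.

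**Figure D4:**
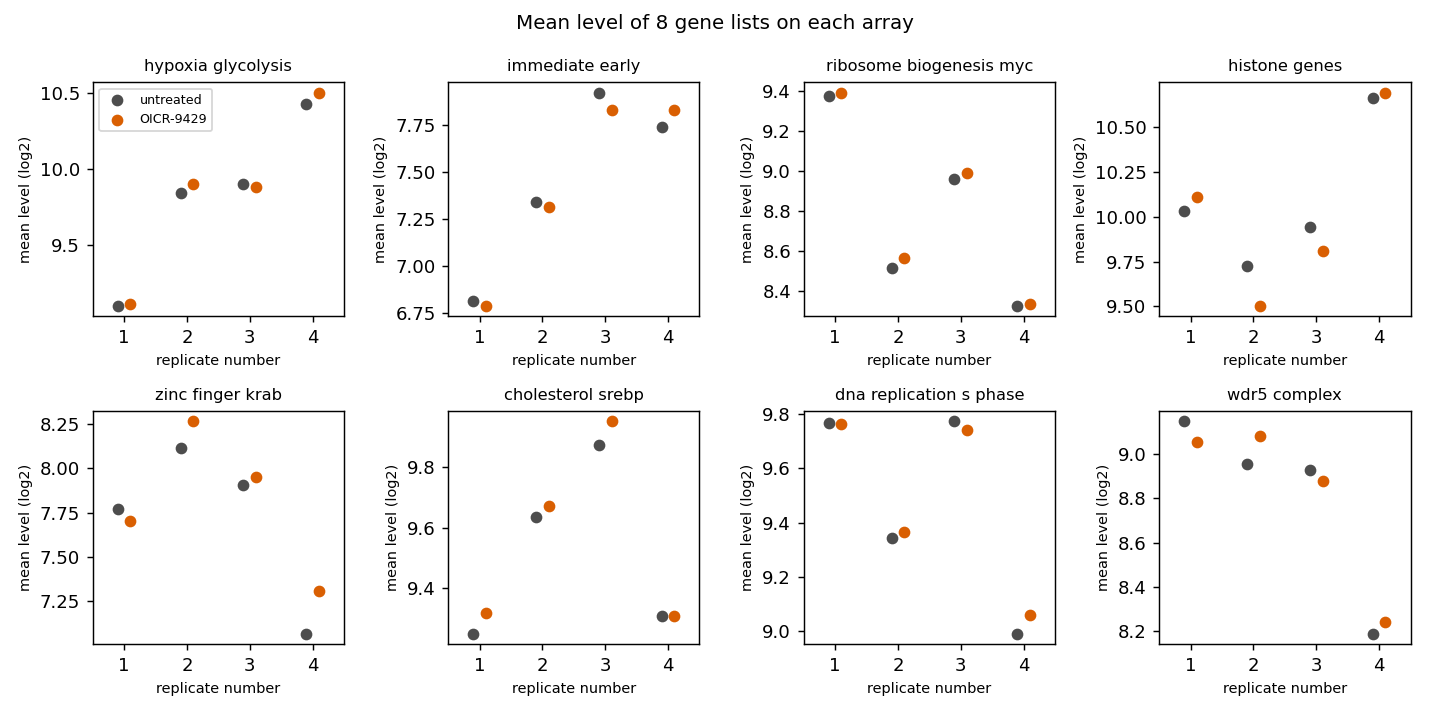
Mean log2 level of 8 gene lists on each of the 8 arrays, by replicate number, with grey for untreated and orange for OICR-9429. The panels have separate vertical axes that do not start at 0, and arrays of the same number lie close together.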

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

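The comparison of the count at unadjusted p with other splits of the arrays was planned, and every other test in this part was chosen after the result was seen, as were all limits used to read these tests. In 142 groups of 4 arrays, 7 held 1 array far from the other 3, and chance gives about 7.1 (1 in 20). Of the 7, 6 are arrays of number 4. Its untreated array had a mean level of 6.94 for HOX and MEIS genes (the others 7.43 to 7.51), 9.73 for actin and motility genes (9.95 to 9.99) and 8.95 for heterochromatin and Polycomb genes (9.52 to 9.58). Its treated array had 9.01 for heterochromatin and Polycomb genes (9.55 to 9.61), 8.53 for nuclear envelope genes (8.97 to 9.02) and 9.87 for splicing genes (10.38 to 10.43). The remaining one was CMTM8 in OICR-9429 replicate 2, at 4.87 against 5.37 to 5.47 on the other treated arrays.

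The first pattern is that 0 probe sets changed with OICR-9429. Splits of the 8 arrays into 4 and 4 decide nothing about the 0 calls (highest other 9) and 0 lists (highest other 18), since all 35 of 35 must reach a count of 0, and for the 105 probe sets at unadjusted p under 0.05, which 29 of 35 reached (highest other 4162), chance cannot be excluded. The high counts point to the structure by number: the 8 splits that part all 4 pairs gave 75 to 124 such probe sets, with 2 of the 8 at 105 or more, and the 27 that part fewer gave 219 to 4162. Changes of 2-fold or more hidden by differences between numbers are argued against for most of the array, since with the replicate block 0 probe sets passed and 99.8% of intervals lay within 2-fold. That holds for the measured intensities alone, since it is not known which probe sets had signal over background. Small changes shared by the pairs stay open: the mean correlation of fold changes between pairs was 0.0205, 2 of 8 sign arrangements were as high, and the highest other was 0.0531.

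The second pattern is that number 4 stands apart in both groups. Its arrays had a narrower range of values (SD over probe sets 2.17 and 2.18, the others 2.25 to 2.31), but after a quantile normalization that gives all arrays 1 distribution 10862 probe sets differed at number 4, against 11108 before, with 9675 in both and in the same direction, which argues against that range as the whole cause. RNA quality, culture density and day of work were not tested, because the labels give none of them, and any of these could be the source. Cells of another kind stay open too. The medians of the 5 marker lists at number 4 were 0.11 to 0.41. With an estimated correlation 0 of these lists passed (camera, smallest adjusted p 0.368). The lists are dim (mean levels 5.085 to 6.27), and differences at number 4 correlated with mean level at -0.232 across probe sets. Their rise therefore cannot be told apart from an effect of the narrower range. No biological explanation was tested, since the design names no difference between replicate numbers.

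The third pattern is a one-sided set at number 3, where 77 of 80 probe sets that differed by 2-fold were higher. Spread of single arrays is argued against by 102 probe sets picked as 2-fold higher on the untreated array of number 3 alone. Of these, 79.4% were also highest at number 3 among the treated arrays, where chance gives 25% for arrays that do not pair. The arrays of number 3 pair over all probe sets (correlation of deviations 0.566), so the share restates that pairing for this set. The listed markers of the 5 other kinds of cell did not reach 2-fold. List medians at number 3 lay between -0.12 and 0.0067, and the highest median plus 1 SD over members was 0.241 against 1 for 2-fold. Of 70 members 0 were 2-fold higher, and the highest was THY1, at 0.98. A list median cannot show a few cells that raise single markers, and the limit was chosen after the values were seen. Cells of these kinds are therefore not excluded. Cells of another kind without a list here, or a different state of the same cells, may be the source and stay untested.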

How the results depend on the processing

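The counts of probe sets changed, higher and lower stayed at 0 in 26 of 27 alternatives each. The exception, planned, was an unadjusted p under 0.05 with a 1.5-fold difference, which gave 9, 3 and 6, by its own looser construction. The 105 probe sets at unadjusted p under 0.05 became 37 and 5 with filters at the 25th percentile and the median (fewer probe sets tested), 165 with trend and robust variance, 806 with array weights and 1191 with the replicate block. In block fits added after seeing the data they became 1166 with trend and robust variance, 607 with the median filter, 1482, 942, 1128 and 1033 without pairs 1 to 4, and 1297 with a random block. Leaving out 1 array gave 82 to 271, the highest without OICR-9429 replicate 4. The causes were not tested beyond these constructions.

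The number of lists past the threshold rose from 0 to 1 with the replicate block, and in added block fits to 4 with trend and robust variance (histone, KRAB zinc finger, heat shock and ribosomal protein genes, adjusted p = 0.000139, 0.0172, 0.0172 and 0.0283, camera), 1 with the median filter (histone, 0.000438), 3 without pair 1 (histone, KRAB and ribosomal protein), 1 without pair 3 (KRAB) and 1 without pair 4 (histone). It stayed at 0 without pair 2, and with an estimated correlation or fry, with or without the replicate block (smallest adjusted p with the block 0.885 and 0.583); the later block fits were run at the preset correlation alone. Leaving out 1 array gave 0 to 8: 3, 3, 5 and 5 without untreated replicates 1 to 4, and 4, 2 and 8 without OICR-9429 replicates 1, 2 and 4. Each such fit unbalances a replicate number between groups, as for the WDR5 complexes, low at number 4, which stood at -0.20 without untreated and 0.20 without OICR-9429 replicate 4. Of the 35 lists, 31 changed sign in at least 1 alternative. Those that changed sign and passed the threshold there ran, lowest to highest, from -0.20 to 0.20 for WDR5 complexes, -0.17 to 0.22 for ribosome biogenesis, -0.23 to 0.20 for immediate early, -0.21 to 0.28 for hypoxia, -0.28 to 0.13 for histone, -0.15 to 0.15 for replication, -0.12 to 0.17 for chromatin and -0.10 to 0.091 for oxidative phosphorylation genes. KRAB zinc finger genes passed in 7 of 22 alternatives (adjusted p = 0.000155 to 0.929, camera). Of 99 named genes 0 passed an adjusted p of 0.05 in the 23 settings run for single genes (smallest 0.68, limma), and 3 met the looser unadjusted p with 1.5-fold, KLF4 and KCNK15 among them. Without 1 array, 65 of the 99 fold changes moved by over 1.5 times and 20 changed sign. Apart from the KRAB list, and from KLF4 and GCLC adjusted over their lists alone, the replicate block changed no call. Signal over background is not known from these values and limits the dim genes.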

Other observations

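The tests in this part were chosen after the result was seen. RNF130, a ubiquitin ligase, stood at 8.74 at number 3 against 4.82 at the other numbers, a log2 difference of 3.93 ± 0.12 (SE), NETO2 at a difference of 3.05, PLEKHA1 at 2.99, BEX1 at 2.27 and GFRA1, a receptor subunit for glial-derived neurotrophic factor, at 2.17. The cortical thymocyte markers CD1E, CD1A and CD1B were higher by 2.21, 2.03 and 1.83 on the log2 scale, and the immediate early genes NR4A1, EGR3 and NR4A3 by 2.74, 2.11 and 1.98. With number 4 left out, CD1E, CD1A and CD1B differed by 1.61, 1.66 and 1.53, and RNF130 and NETO2 by 3.285 and 2.515. NR4A1, EGR3 and NR4A3 then differed by 2.755, 2.15 and 1.58. Of the 77 probe sets at least 2-fold higher at number 3, 7 belong to the immediate early list, and 79.2% lay below the median level at the other numbers. Among the 7 are JUN and EGR1, which are low at number 1. With number 1 left out they differed by 0.83 and 0.39 at number 3. For 70 of the 77, both arrays of number 3 lay above every other array. At number 4 RNF130 and CD1E differed by -3.02 and -2.33 from the other numbers, and by -1.93 and -1.80 when number 3 was left out.

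Number 2 had higher levels of ASNS (asparagine synthetase, 2.57 on the log2 scale), SLC7A11 (the cystine transporter, 2.44), VLDLR (1.86) and ASS1 (argininosuccinate synthase, 1.94), and, against numbers that include number 4, lower histone genes (33 of 48 lower, median -0.47) and higher KRAB zinc finger genes (27 of 39, median 0.59). Without number 4 these medians were -0.30 and 0.38. Of 21 sterol synthesis genes, 1, 9, 8 and 5 were higher and 11, 4, 0 and 11 lower at numbers 1 to 4, with list medians of -0.45, 0.27, 0.50 and -0.44 (camera, adjusted p = 0.312, 0.451, 0.268 and 0.432 with an estimated correlation). Without number 3 the medians at numbers 1, 2 and 4 were -0.26, 0.51 and -0.16. Each of the single genes named here passed limma's test at its number, and 0 of the list tests passed with an estimated correlation.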
